A study of Gallus gallus with 8 samples.

How the data were processed

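Hypothalamic RNA of chickens from a fat line (FL) and a lean line (LL) was compared at 4 ages, weeks 1, 3, 5 and 7, on DEL-MAR spotted cDNA arrays. Sample titles gave the line and the age. The series design text gives 4 biological replicates for each of the 8 groups, and 32 arrays were used. Per the labels' protocols, every sample was labelled with Cy3 and hybridised against one Cy5-labelled pool made of equal parts of all the RNA samples. All arrays therefore had the same dye orientation, and a positive log2 ratio means more of a transcript in the sample than in the pool. The lowest correlation between the log2 ratios of 2 arrays was -0.16 over all clones and -0.38 over the clones tested (496 pairs), and the direction was kept because the labels state the dyes. The sex of the birds is not given in the sources used here.

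Per the file headers, each array's deposited file holds raw and local background intensity in both channels, the area and flags of every spot, a Cy3 intensity that the authors normalized to the Cy5 channel, and the authors' log2 ratio of these. The scanner, image software, normalization method and spot filters are not given in the sources used here. Raw intensity was a sum over the pixels of a spot and was divided by the spot area. Whether the deposited raw intensity still contained the local background could not be settled, so background subtraction was also left out as an alternative. The authors' series table gives 1 log2 ratio per group. All 64503 of its values compared by place in the table lay within 0.005 of the mean of the 4 arrays, against 1775 of 30053 compared by spot name, so spot names differ between the table and the array files. By the array files' names, spots of ribosomal protein genes had a median log2 brightness of 12.32 (80 spots), against 10.32 by the table's names and 10.59 over all 10478 named spots. Spots that share an accession correlated in brightness with a Spearman rho of 0.405 (702 pairs, across spots) by the array files' names and 0.0191 (657 pairs) by the table's. The array files' names were used, and the series table, put in their order, served as an alternative.

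Gene symbols came from the platform annotation, which lists 10601 of the 19200 spots with 1 symbol, 0 with several, and leaves 8599 unnamed here. A further 123 spots were left unnamed because their 2 accessions cover many unlike spots. Of the 10478 named spots, 10332 matched the current chicken gene table by gene number, and 0 symbols changed. Spots of one accession were averaged (472 accessions, 1004 spots), which gave 17708 clones. Where a gene had several clones, the brightest stood for it, and the text says where another clone of a named gene went the other way. Clones of APOA1, STK10, CLC2DL5, EPRS and TRMT2A disagreed, and the identity of the printed clones was not checked here, so a value belongs to its clone and the gene's name is that of the annotation.

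Intensities were corrected with the normexp method (offset 50), converted to log2(Cy3/Cy5) and normalized within each array by global loess (span 0.3, 4 iterations) with limma 3.58.1 in R 4.3.3. The 960 empty spots in the last sub-row of the blocks had weight 0 in the loess. Spots whose quality letters were A, X, Y or Z were left out, because the files mark quality with letters, not the negative numbers that had been assumed. The files hold no key to the letters, so which of them mark a poor spot was itself an assumption. A spot counted as above background when its Cy3 signal exceeded the 95th percentile of the empty spots of its array. This took the place of a planned rule based on the SD of the background, which was not used here. A clone was tested when it was above background on at least 3 of the 4 arrays of at least 1 group and had at least 2 values in every group. That left 7917 clones, 4769 of them named, for 3740 genes, with 3.00% of their values missing. Arrays are summarised by the median Cy3 signal over local background, and their number limits the precision.

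One limma model with a mean for each of the 8 groups gave every comparison (24 residual degrees of freedom when no value was missing, 3.14 prior degrees of freedom, median residual SD 0.21). Line effects are FL minus LL, across the ages and at each age. The interaction is a moderated F test of whether the line effect at weeks 3, 5 and 7 differed from that at week 1. Age effects are differences between weeks averaged over the lines, and also within each line between weeks 7 and 1. All tests were two-sided, with Benjamini-Hochberg adjustment over the clones and a threshold of 0.05. Errors of log2 differences are standard errors of the model. An FL array counts as showing a line effect when its log2 ratio lies on that side of the LL mean at its age, and a week 7 array as showing an age effect when it lies on that side of the week 1 mean of its line (likewise week 3 arrays for the step from week 1). Where no array of a group measured a clone above background, the size of its difference is uncertain. A fold from the Cy3 channel (Cy3 fold) is then given as a point estimate without error, not as a guaranteed minimum. The brighter group's mean normalized log2 Cy3 level was set against the dim group's. In the dim group each array took the higher of its own value and the lowest signal among spots above background. For ENPP2, RNF208 at week 5 and the unnamed clone across the ages, this floor changed nothing. Such folds rest on the Cy3 channel after loess and Aquantile scaling and are open to dye bias. Where the Cy3 fold exceeded the fold of the log2 ratios, or a group on the brighter side had no array above background, no Cy3 fold is given.

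Fixed gene lists (26) covered peptides and receptors of feeding, other signalling, cell types, and metabolism. Lists with at least 5 genes tested (23) were compared with all other genes by limma's camera with a preset correlation of 0.01, and again with the correlation estimated from the data. Missing values were set to the group mean for camera. The groups, the tests, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule named the 10 largest rises and falls across the ages and with age, and the 3 largest at each week, among named genes that passed and kept their sign over the weeks or in both lines. It took 1 clone per gene, the 5 smallest p-values where none passed, and members of the fixed lists that passed as examples. A few feeding and glial genes were also fixed by name. Other genes named in the text, among them list members that did not pass over all genes, were chosen after their values were seen.

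The tests were checked on simulated data built on the 7917 clones, with 100 clones changed by a log2 difference of 1 and 100 by 0.5. The line effect across the ages recovered 100% and 82% of them, the line effect at week 1 recovered 85% and 41%, the age effect between weeks 7 and 1 recovered 96% and 63%, and the interaction recovered 65% and 11%. Unchanged clones called were 13, 4, 12 and 4. The simulated noise was independent between clones and between arrays, and each clone had the same spread on all arrays. The rates therefore do not cover arrays of unlike quality or spread shared between arrays or clones. Alternatives changed the background correction, the loess, scaling between arrays, the filter on dim clones, the flags, the array weights, the replicate number as a block, the arrays in the fit and the threshold, and left out each array in turn. Aquantile scaling leaves log ratios unchanged, so only the scale method was run between arrays. A block for scan day or slide was not run because the file headers give neither. Figures were drawn with matplotlib 3.10.9.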

Results

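Gene expression in the hypothalamus, the brain region that governs feeding and energy balance, was measured in a fat line (FL) and a lean line (LL) of chickens while adiposity developed. Each of the 8 groups, FL and LL at weeks 1, 3, 5 and 7, held 4 arrays, and each array compared the RNA of 1 sample with a pool of all the samples. The arrays measured between 2585 and 11994 clones above background, which is 14.6% to 67.7% of the clones on them. Their median Cy3 signal lay between 2.57 and 8.45 times the local background. The FL arrays of week 1 had the lowest mean, 3.96 ± 0.718 (SD, n = 4), against 6.05 ± 1.76 in LL at week 1. Between 11.4% and 29.0% of the spots of an array were left out for their quality letters, whose meaning is not given in the sources used here. Signal also differed by replicate number, with means of 3.63 ± 0.709, 4.36 ± 0.694, 5.67 ± 1.18 and 6.84 ± 1.22 for numbers 1 to 4 (SD, n = 8 arrays each, permutation p = 2e-05, 100000 resamples within groups, two-sided). The first principal component of the log ratios held 28.2% of the variance and the second 14.5% (5491 clones).

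**Figure D1:**
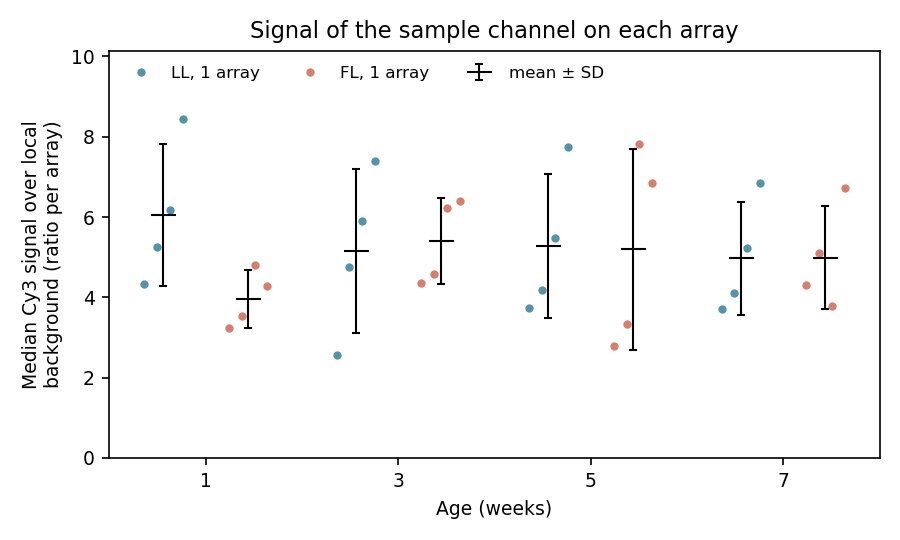
Median Cy3 signal over local background (ratio, vertical axis) of each array by age in weeks, with LL and FL arrays as points in the order of their replicate numbers and the mean ± SD of 4 arrays in black. The FL arrays of week 1 averaged 3.96 and the LL arrays of week 1 averaged 6.05.

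Across the 4 ages, few transcripts separated the lines. CRTC1, a coactivator of the cAMP response factor CREB that takes part in the hypothalamic control of feeding, was lower in FL, with a log2 difference of -0.45 ± 0.09 (SE, 15 of 16 FL arrays, adjusted p = 0.0367, limma). No FL array measured it above background at weeks 1, 3 and 7, so the size of its difference is uncertain (Cy3 fold 1.26). CLC2DL5, a gene of the C-type lectin-like family, was lower in FL (log2 -0.57, 16 of 16 arrays, adjusted p = 0.00282), while the other clones of the gene gave -0.05 and 0.25. No array measured that clone above background in FL at weeks 1, 3 and 7 or in LL at week 7, so the size of its difference is uncertain. The other clones that passed had no gene name. Of these, 1 was lower in FL (log2 -0.69, Cy3 fold 1.60, 15 of 15 arrays, adjusted p = 0.00282), with no FL array above background at weeks 3 and 7. The other differed by -0.54 (13 of 14 arrays, adjusted p = 0.0367). CLC2DL5 and the unnamed clones fell outside the naming rule and were chosen after their values were seen. In all, 4 of 7917 clones passed, 0 higher and 4 lower in FL, and 386 had an unadjusted p under 0.05 against 395.85 expected by chance. CRTC1 no longer passed in 23 of 32 fits that left out 1 array, and kept passing without LL week 3 replicate 4, LL week 7 replicate 3, FL week 1 replicate 3 or 4, FL week 3 replicate 3, FL week 5 replicate 2 or 4, and FL week 7 replicate 1 or 2. By limma, 0 clones passed with the stricter filter on dim clones (203 at an unadjusted p under 0.05) or with the authors' log2 ratios (421), and 2 passed without LL week 1 replicate 2, 3 or 4, LL week 3 replicate 3, LL week 5 replicate 2 or 4, LL week 7 replicate 1, 2 or 4, FL week 3 replicate 1, or FL week 7 replicate 3. The 4 called clones were not tested with the stricter filter or the authors' log2 ratios, so the 0 there is not a failed retest.

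None of the 26 fixed gene lists had a member that passed across the ages, over all genes or adjusted over the list alone. The list of immature neurons and neurite outgrowth was lower in FL as a group when the ages were averaged, and its mean was -0.37 at week 1, 0.04 at week 3, -0.04 at week 5 and -0.11 at week 7. Of its 16 genes tested, 12 had negative differences, with a mean of -0.12 ± 0.15 (SD over genes) and an adjusted p of 0.000514 by camera. The adjusted p was 0.161 with an estimated correlation. Among its members, the neuronal tubulin TUBB3 gave -0.39, the microtubule regulator STMN1 -0.36 and the tubulin TUBA1A -0.31. The anterior pituitary list, whose genes the neighbouring gland expresses, did not pass (adjusted p = 0.0572, and 0.161 with an estimated correlation), and 7 of its 8 genes had positive differences, including GH at 0.25 and CGA at 0.25. The other 21 lists tested by camera did not pass. The number of lists that passed was 3 without LL week 1 replicate 3, FL week 5 replicate 4 or FL week 7 replicate 4, and 2 without LL week 3 replicate 1, 2 or 3, LL week 5 replicate 2, FL week 1 replicate 1, FL week 3 replicate 1 or 2, FL week 5 replicate 1, or FL week 7 replicate 1.

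At week 1, the transcripts that passed between the lines were lower in FL with 1 exception, while the clones at an unadjusted p under 0.05 were 621 higher and 777 lower. SGIP1, an endocytic adaptor of neurons, was 2.0-fold lower in FL (log2 -1.0 ± 0.16, SE, 4 of 4 FL arrays, adjusted p = 0.00841, limma). ATP6V1B2, a subunit of the vacuolar proton pump that acidifies synaptic vesicles and lysosomes, was 1.95-fold lower (log2 -0.96 ± 0.18, 4 of 4 arrays, adjusted p = 0.0144). VCP, an ATPase that extracts proteins for degradation, was 1.71-fold lower (log2 -0.78 ± 0.15, 4 of 4 arrays, adjusted p = 0.0173), and its other clone gave -0.67. SGIP1 passed whichever single array was left out. ATP6V1B2 was lost without LL week 1 replicate 1 or 4 or FL week 1 replicate 2, and VCP without LL week 1 replicate 1, 2 or 4 or FL week 1 replicate 4. The group means of SGIP1 were 0.03 ± 0.13 in LL and -0.98 ± 0.31 in FL at week 1 (SD, n = 4 arrays each, log2 ratio to the pool), and 0.33 ± 0.16 and 0.09 ± 0.35 at week 7.

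Further genes that passed at week 1 were named after their values were seen. They include APLP2, a relative of the amyloid precursor protein (log2 -1.14, adjusted p = 0.00912), and the RNA-binding protein HNRNPH1 (-1.11, adjusted p = 0.00841). Other clones gave -0.35 for APLP2 and -0.32 and -0.15 for HNRNPH1. The collapsin response mediators DPYSL2 and CRMP1, which steer growing axons, gave -1.22 (adjusted p = 0.0376) and -1.19 (adjusted p = 0.0369), and their other clones -0.65 and -1.0. NAPB, which recycles the complexes that fuse synaptic vesicles, gave -0.84 (adjusted p = 0.0144), with other clones at -0.53 and 0.00. Each of these was lower in 4 of 4 FL arrays. CRMP1 and the poly(A)-binding protein PABPC1 (-0.97, adjusted p = 0.0237, 4 of 4 arrays) were not above background on any FL array of week 1, so their size there is uncertain. The other clones of PABPC1 gave -0.39, -0.42 and -0.05. In fits that left out 1 array, CRMP1 and DPYSL2 were lost in 9 of 32 each, PABPC1 in 6, NAPB in 2, APLP2 in 1 and HNRNPH1 in 0. In all, 19 of 7917 clones passed, 1 higher in FL and 18 lower, from 14 named genes, and 1398 clones had an unadjusted p under 0.05. The 1 clone that was higher had no gene name (log2 0.48, 4 of 4 arrays, adjusted p = 0.0471). With each array's signal as a covariate, 0 clones passed by limma and 755 had an unadjusted p under 0.05. The 19 clones kept a median of 89.3% of their log2 difference. The authors' log2 ratios gave 1 clone, and the stricter filter on dim clones and scaling between arrays gave 3 each. Several of the 19 clones were not tested with the authors' log2 ratios or with the stricter filter. With only the 8 arrays of week 1 in the fit, 9 clones passed, of which 1 was among the 19. Leaving out 1 array gave 2 and 11 clones (LL week 1 replicates 1 and 4), 91, 7, 29 and 11 (FL week 1 replicates 1 to 4), 82 (LL week 3 replicate 1) and 176 (FL week 7 replicate 3).

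**Figure D2:**
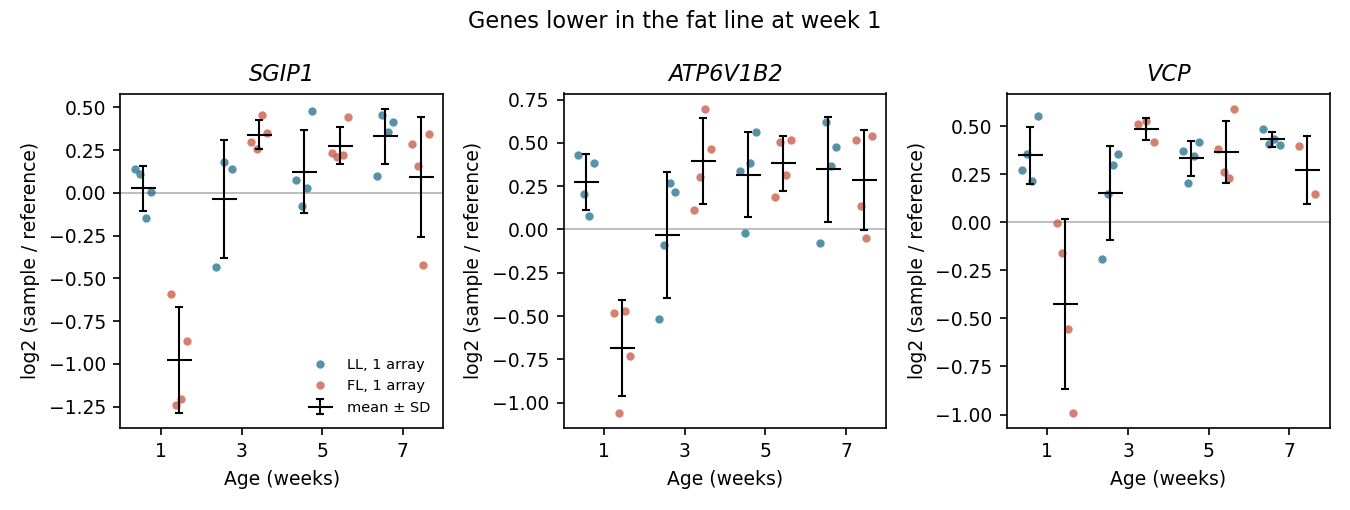
Log2 ratio of the sample to the reference pool (vertical axis) for SGIP1, ATP6V1B2 and VCP by age in weeks, with each array as a point (LL blue, FL red) and the mean ± SD in black. At week 1 the FL arrays lie below the LL arrays, with a mean of -0.98 for SGIP1 against 0.03 in LL.

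The fixed lists at week 1 were read by camera only after the counts were seen. Immature neurons and neurite outgrowth, whose difference across the ages includes these arrays, was lower in FL, with a mean of -0.37 ± 0.42 (SD over 16 genes, 12 negative) and an adjusted p of 0.000268, or 0.246 with an estimated correlation. None of its members passed over all genes with the clone that stood for the gene, and 5 were lower adjusted over the list alone: TUBB3 (-1.05), CRMP1 (-1.0), TUBA1A (-0.93), DPYSL2 (-0.65) and STMN2 (-0.59). Cytosolic ribosomal proteins were lower as a group, at -0.17 ± 0.38 over 36 genes (25 negative, adjusted p = 0.00234, or 0.449 with an estimated correlation). RPL3 (-0.75) and RPS3 (-0.39) were lower adjusted over the list alone, and 0 members passed over all genes. The signal of the FL arrays at week 1 was the lowest of all groups, as given above.

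At weeks 3, 5 and 7, 0 clones passed between the lines by limma. Other settings gave 1 at week 3 (without FL week 3 replicate 1), 3 and 4 at weeks 5 and 7 (array weights), 1 at week 5 (X, Y and A quality letters kept) and 1 at week 7 (no filter on dim clones). Unadjusted p-values under 0.05 were found for 180, 224 and 285 clones, fewer than the 395.85 expected by chance. The genes with the smallest p-values at week 3 were the ribosomal protein RPS21 (log2 0.43), ARPP19 (0.40), the proton pump subunit ATP6V1A (0.44, with -0.31 in its other clone), RNF212B (-0.22) and CISD1 (0.50, 3 of 3 arrays), each with an adjusted p of 0.999. All but CISD1 showed their direction in 4 of 4 FL arrays. At week 5 they were RNF208 (log2 0.53, Cy3 fold 1.33), RPS21 (-0.45), ZEB1 (0.46), TTYH3 (1.27) and DOHH (0.42), each with an adjusted p of 1 and 4 of 4 arrays in their direction. At week 7, again in 4 of 4 arrays each, they were the adhesion molecule CADM3 (0.57, adjusted p = 0.775, with -0.12 in its other clone), DDX46 (-0.67), CECR5L (0.41), RNF208 (-0.55) and TRDN (0.42). No FL array of week 7 measured RNF208 or TRDN above background, so their sizes are uncertain. The Cy3 fold of RNF208 was 0.96, so the Cy3 channel alone did not show it lower in FL. FL was the brighter side for TRDN, so no Cy3 fold is given. The spread of the line effect over all clones was 0.30 at week 1 and 0.17, 0.18 and 0.19 at weeks 3, 5 and 7 (SD of log2 differences).

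Whether the line difference changed with age was tested by the interaction. It passed for 0 of 7917 clones by limma, with 542 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0967. SGIP1 and RNF208 had the smallest p-values (adjusted p = 0.0967 each), followed by ATP6V1B2 (0.0985), RPS21 (0.118) and VCP (0.194), and none of them passed. The week 1 differences of SGIP1, ATP6V1B2 and VCP are therefore not shown to be limited to that age. Leaving out FL week 7 replicate 3 gave 30 clones, leaving out FL week 1 replicate 2 gave 3, and leaving out FL week 1 replicate 1, FL week 5 replicate 1 or LL week 5 replicate 4 gave 1 each. Array weights gave 5, as did the fit without the 3 arrays that stand apart (LL week 3 replicate 1, FL week 1 replicate 4 and FL week 7 replicate 3). The replicate number as a block gave 2. Across clones, which are not independent replicates, the line effects of 2 weeks correlated with an r between -0.27 (weeks 1 and 3) and 0.41 (weeks 1 and 7), with a mean of 0.00 ± 0.28 (SD, 6 pairs of weeks).

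Age changed more transcripts than line. Between weeks 1 and 7, APOA1, the main protein of high-density lipoprotein, rose 1.97-fold (log2 0.98 ± 0.16, SE, 8 of 8 week 7 arrays, adjusted p = 0.00141, limma), while its other clone gave -0.33. ENPP2, the enzyme autotaxin made by oligodendrocytes and choroid plexus, rose (log2 1.24 ± 0.26, Cy3 fold 1.91, 8 of 8 arrays, adjusted p = 0.0128), with 0.27 in its other clone. No FL array of week 1 measured ENPP2 above background, so the size of its rise is uncertain. HBBA, a beta-type globin of red blood cells, fell with a fold of 2.55 (log2 -1.35 ± 0.15, 8 of 8 arrays, adjusted p = 6.99e-06). TOP2A, the topoisomerase of dividing cells, fell with a fold of 2.14 (log2 -1.10 ± 0.19, 8 of 8 arrays, adjusted p = 0.00191). TAC1, the precursor of substance P, rose by a smaller amount (log2 0.26 ± 0.06, 8 of 8 arrays, adjusted p = 0.0235).

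Other genes that rose between weeks 1 and 7 were the myosin phosphatase partner MPRIP (1.05, adjusted p = 0.0457), the transcription factor ZFHX3 (0.99, adjusted p = 0.0403), UFL1 (0.97, adjusted p = 0.0259) and NDRG4 (0.93, adjusted p = 0.012). GUCY1A3, a subunit of the nitric oxide receptor, rose by 0.76 (adjusted p = 0.012), ABHD12 by 0.75 (adjusted p = 0.000951), the proteoglycan GPC4 by 0.73 (adjusted p = 0.0292) and TMEM104 by 0.69 (adjusted p = 0.0269). Each of these 8 rose in all the week 7 arrays that measured it, between 6 and 8, and other clones went the other way for NDRG4 (-0.06) and TMEM104 (-0.01). Other clones of the same sign gave 0.04 for ABHD12, 0.17 and 0.27 for GPC4 and 0.18 for NDRG4. Genes that fell were PCMT1L (-0.76, adjusted p = 0.0255), OXCT1, an enzyme of ketone body use (-0.48, adjusted p = 0.0207), RER1 (-0.48, adjusted p = 0.0146, and -0.46 in its other clone), CMTM3 (-0.47, adjusted p = 0.02, and -0.17 in its other clone), FAM134C (-0.46, adjusted p = 0.0457) and TMBIM1 (-0.42, adjusted p = 0.0292). TRMT2A (-0.50, adjusted p = 0.0457) and EPRS, a tRNA synthetase (-0.52, adjusted p = 0.00071, of uncertain size because no FL array was above background at week 7), also fell, while other clones gave 0.26 for TRMT2A and 0.53 and 0.08 for EPRS. FAM134C was lower in 5 of 6 arrays, TRMT2A in 7 of 8, RER1 in 6 of 6 and the others in 8 of 8. In fits that left out 1 array, TRMT2A was lost in 24 of 32, FAM134C in 19, MPRIP in 18, ZFHX3 and GPC4 in 10 each, TMBIM1 in 8, PCMT1L in 5, UFL1, TMEM104, OXCT1 and CMTM3 in 3 each, RER1 in 1, and NDRG4, GUCY1A3, ABHD12 and EPRS in 0.

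In all, 202 of 7917 clones passed between weeks 1 and 7, 123 higher and 79 lower at week 7, from 117 named genes. At an unadjusted p under 0.05 there were 1499, 720 higher and 779 lower, and without background subtraction the calls were 247 higher and 242 lower. All 202 moved in the same direction in both lines. They were called on the average of the lines, which favours such agreement, so it is not a separate check. Of the clones called between the lines at week 1, 12 were among the 202, and both comparisons use the FL arrays of week 1. The count lay between 25, with only the 16 arrays of weeks 1 and 7 in the fit, and 1011, with array weights. It was 312, 80 and 80 without LL week 1 replicates 2, 3 and 4, 103 without LL week 7 replicate 2, 478, 83 and 115 without FL week 1 replicates 1, 2 and 3, and 65, 79, 535 and 90 without FL week 7 replicates 1 to 4. The clone with the largest fitted change, unnamed and chosen after its value was seen, was lower at week 7 (log2 -3.46 ± 0.24, 8 of 8 arrays, adjusted p = 3.39e-10), where no array measured it above background, so the size of this change is uncertain. It was printed at sub-row 9 and column 5 of block 25, and the clones at that place in blocks 26, 27 and 28 were NFASC (-0.46, adjusted p = 0.055, not passed), TOP2A and STK10. STK10, a kinase also named after its value was seen, fell with a fold of 4.02 (log2 -2.01 ± 0.19, 7 of 7 arrays, adjusted p = 3.14e-07), and its other clone gave 0.04. Among the clones with the smallest p-values, the chaperone CLU, which astrocytes secrete, rose (0.46 ± 0.06, 8 of 8 arrays, adjusted p = 0.000139), with 0.32 in its other clone.

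**Figure D3:**
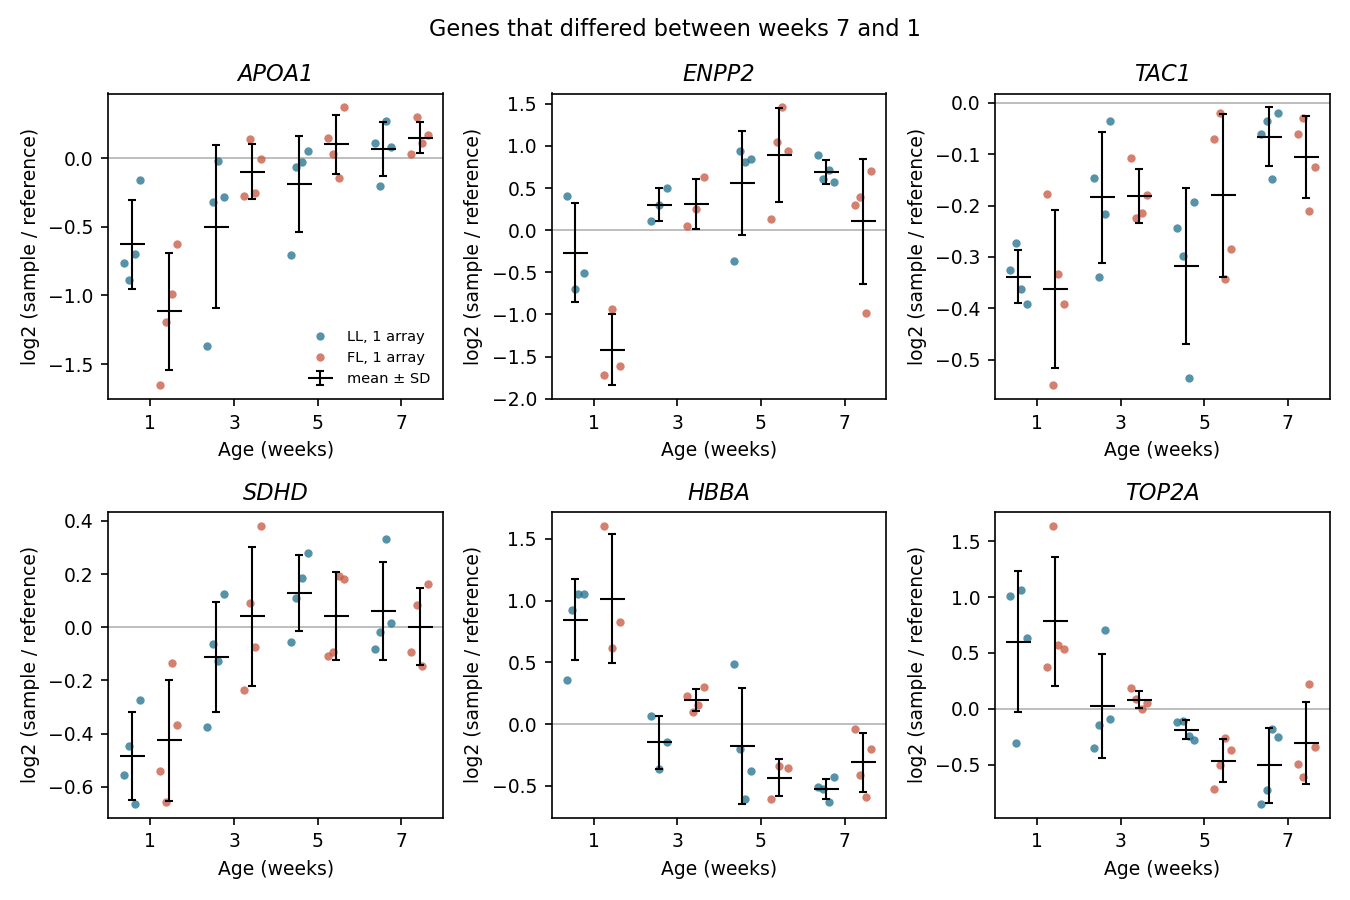
Log2 ratio of the sample to the reference pool (vertical axis) for 6 genes by age in weeks, with each array as a point (LL blue, FL red) and the mean ± SD in black. APOA1, ENPP2, TAC1 and SDHD were higher at week 7 than at week 1, and HBBA and TOP2A were lower, with log2 differences of -1.35 and -1.10.

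Members of 10 of the 26 fixed lists changed between weeks 1 and 7, with 1 gene passing in each by the clone that stood for the gene. Of 6 feeding neuropeptides, TAC1 rose, and adjusted over the list alone TAC1 rose and NMU (-0.28) fell. Of 8 neurosecretory genes, CPE, which trims peptide hormones, rose (0.44 ± 0.12, 8 of 8 arrays, adjusted p = 0.0403), while its other clone gave -0.06, and 1 passed adjusted over the list alone. Of 30 oxidative phosphorylation genes, SDHD rose (0.49 ± 0.10, 8 of 8 arrays, adjusted p = 0.00725), and 3 rose adjusted over the list alone, including COX6C (0.65) and ATP5I (0.37). Of 19 oligodendrocyte and myelin genes, ENPP2 rose, and 2 rose and 2 fell adjusted over the list alone, with CRYAB at 0.35, SGK1 at -0.46 and NKX6-2 at -0.39. Of 11 astrocyte and radial glia genes, APOA1 rose, and 1 passed adjusted over the list alone. CLU, also of this list, passed with a clone that did not stand for the gene, as given above. Of 4 circadian clock genes, HLF rose (0.36 ± 0.09, 7 of 7 arrays, adjusted p = 0.0271), and 1 passed adjusted over the list alone. Of 36 ribosomal protein genes, RPL21 fell (-0.40 ± 0.11, 8 of 8 arrays, adjusted p = 0.0493), and of 15 cholesterol synthesis genes, CYP51A1 fell (-0.21 ± 0.05, 8 of 8 arrays, adjusted p = 0.0269), with 1 each adjusted over the list alone. In fits that left out 1 array, TAC1 was lost in 5 of 32, CPE in 13, RPL21 in 26, CYP51A1 in 4 and HLF in 7, and SDHD, APOA1, ENPP2, HBBA and TOP2A in 0.

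Genes of red blood cells and of dividing cells were the other lists with a member that passed. Of 6 erythrocyte genes, HBBA fell, and adjusted over the list alone HBBA and the alpha globin HBA1 (-0.31) fell. Of 16 cell cycle genes, TOP2A fell, and adjusted over the list alone TOP2A and the thymidylate synthase TYMS (-0.18) fell. The cell cycle list was the only one of 23 to pass by camera, with a mean of -0.18 ± 0.29 (SD over genes, 13 of 16 negative) and an adjusted p of 0.0376, or 0.0572 with an estimated correlation. Without TOP2A, whose spot lay beside the clone with the largest fitted change, 15 genes gave an adjusted p of 0.244, so the call rests on TOP2A. The call was also lost without LL week 1 replicate 3, LL week 7 replicate 1 or 2, or FL week 1 replicate 1, 3 or 4. No member passed in the other 16 lists by the clone that stood for its gene. They held metabolic hormone receptors, anterior pituitary genes, insulin and leptin signalling, GABA, glutamate and monoamine signalling, synaptic vesicles, microglia and choroid plexus. They also held blood vessels, immature neurons, extracellular matrix, fatty acid metabolism, heat shock, the thyroid axis and immediate early genes.

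**Figure D4:**
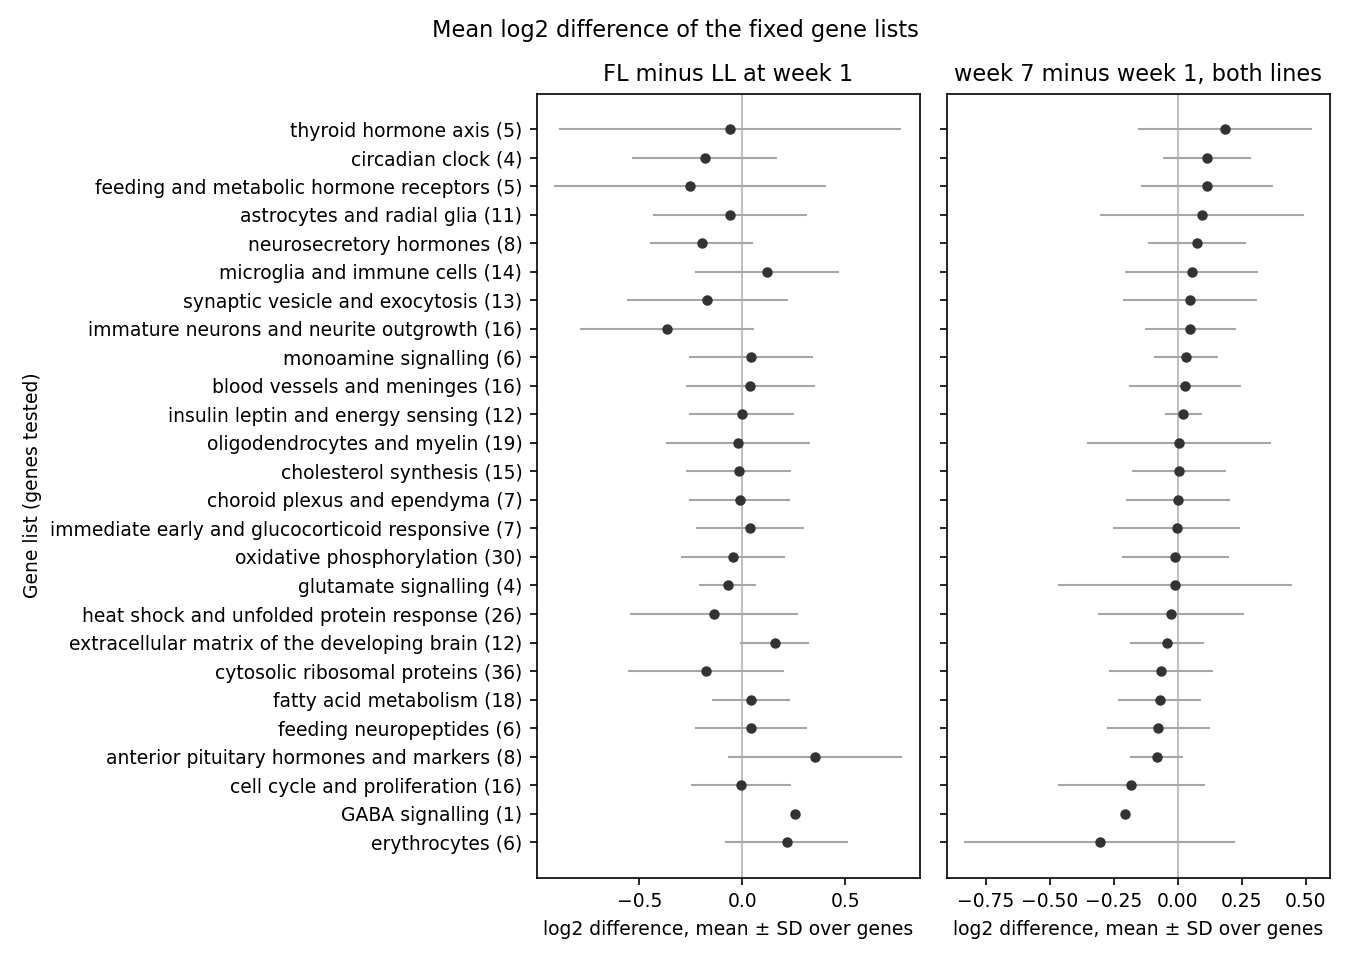
Mean log2 difference of the tested genes of each of the 26 fixed lists (horizontal axis, bars are the SD over genes, genes tested in brackets), for FL minus LL at week 1 on the left and week 7 minus week 1 on the right. Immature neurons and neurite outgrowth averaged -0.37 at week 1 between the lines, and cell cycle and proliferation averaged -0.18 with age.

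The steps between ages differed in how many clones passed. From week 1 to week 3, 11 clones changed, 6 higher and 5 lower, with 962 at an unadjusted p under 0.05. They include, named after their values were seen, HBBA (-0.91, 7 of 7 week 3 arrays, adjusted p = 0.0102), SGIP1 (0.63, 6 of 7, adjusted p = 0.0179), the calcium-binding protein NECAB1 (0.52, 6 of 8, adjusted p = 0.0137) and the kinase WNK1 (0.69, 7 of 8, adjusted p = 0.027). By line, HBBA differed by -0.82 in FL and -0.99 in LL, SGIP1 by 1.32 and -0.06, NECAB1 by 0.90 and 0.14, and WNK1 by 1.24 and 0.13, so for the last 3 the averages come mostly from FL. From week 3 to week 5, 0 clones passed by limma (157 at an unadjusted p under 0.05), and from week 5 to week 7, 0 passed (80 at an unadjusted p under 0.05). The first of these was 2 without FL week 5 replicate 3 and 1 without LL week 5 replicate 2 or FL week 7 replicate 2, 3 or 4. The test over all ages together found 73 clones, with 950 at an unadjusted p under 0.05. From week 1 to week 3, the count was 5 without LL week 1 replicate 3 or LL week 3 replicate 4, 6 without LL week 3 replicate 3, 7 without LL week 1 replicate 4, 23 without LL week 3 replicate 2, 76 without FL week 1 replicate 1 and 53 without FL week 7 replicate 3. Over all ages it was 27 without LL week 1 replicate 3 or 4, 46 and 42 without LL week 5 replicates 3 and 4, 208, 37, 40 and 44 without FL week 1 replicates 1 to 4, 43 without FL week 5 replicate 4, and 48, 158 and 48 without FL week 7 replicates 1, 3 and 4.

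Within FL, 86 clones differed between weeks 7 and 1, 56 higher and 30 lower, and within LL 6 did, 2 higher and 4 lower, and 5 passed in both lines. At an unadjusted p under 0.05 there were 1148 in FL, 507 higher and 641 lower, and 744 in LL, 468 higher and 276 lower. HBBA fell in both, by 1.33 in FL (adjusted p = 0.00244) and by 1.37 in LL (adjusted p = 0.0015) on the log2 scale, in 4 of 4 arrays of each. Of the 86 clones, 84 had the same direction in LL, and the interaction passed for 0 clones, so a difference between the lines in their change with age is not shown. The FL count was 281, 26 and 55 without FL week 1 replicates 1, 2 and 3, and 20, 24, 414 and 20 without FL week 7 replicates 1 to 4. The LL count was 3 without LL week 7 replicate 3. With only the groups compared in the fit, 1 clone passed in FL and 2 in LL. The stricter filter on dim clones gave 9 in FL, and array weights gave 476 in FL and 112 in LL. Median centring gave 42 higher and 52 lower in FL. Of 35 groupings of the FL arrays of these ages, 4 gave a count as large as 86, the real one included, and the highest other was 715.

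Genes fixed by name as central to feeding or to glia did not pass in any comparison made of them with all arrays and the planned processing. POMC, the precursor of the melanocortin peptides that restrain feeding, differed by 0.01 ± 0.06 between the lines across the ages and by -0.16 ± 0.08 with age (adjusted p = 0.961 and 0.283, 7 of 16 FL arrays and 7 of 8 week 7 arrays), and its other clone gave 0.09 with age. The insulin receptor INSR gave 0.11 ± 0.12 and -0.04 ± 0.17, and the thyroid hormone carrier TTR 0.13 ± 0.17 and 0.03 ± 0.23. The myelin gene MBP gave -0.16 ± 0.11 and -0.03 ± 0.15, with 0.18 in its other clone with age, and the astrocyte gene GFAP -0.03 ± 0.15 and 0.55 ± 0.21 (adjusted p = 0.154 with age, 7 of 8 arrays). With age, GFAP passed with array weights, with the authors' log2 ratios and without FL week 1 replicate 3 or FL week 7 replicate 3. Its adjusted p lay between 0.0371 and 0.293 over all settings. Under some settings the sign turned for POMC and GFAP across the ages and for INSR, MBP and TTR with age. NPY and the leptin receptor LEPR each had 1 clone on the array, which did not meet the signal filter.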

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

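The tests of blood and of print position were chosen after the results were seen, as were the array signal as a covariate and the fit without the 3 arrays that stand apart.

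A single array stood far from the other 3 of its group in 7 of the 120 groups examined for named genes, and chance sets apart about 1 in 20 groups, which is 6 here. ABHD12 was at 1.06 in LL week 7 replicate 3, with the others between 0.53 and 0.61 (log2 ratio to the pool, here and in what follows). GPC4 was at -0.25 in FL week 7 replicate 3, with the others between -0.03 and 0.02. CMTM3 was at 0.43 in the same array, with the others between 0.00 and 0.07. TOP2A was at 1.64 in FL week 1 replicate 2, with the others between 0.38 and 0.58. CYP51A1 was at 0.19 in that array, with the others between 0.07 and 0.08. TRMT2A was at 0.32 in LL week 7 replicate 1, with the others between -0.22 and -0.16. CPE was at 0.023 in FL week 1 replicate 1, with the others between -0.66 and -0.55.

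At week 1, SGIP1, ATP6V1B2, VCP and other genes were lower in FL, and the FL arrays of that age had the lowest signal over background. With the array signal as a covariate, the 19 called clones kept a median of 89.3% of their log2 difference (median size 0.97 before and 0.89 after, median SE 0.18 in both), which argues against array signal as the whole of the difference. The call itself ended, with 0 clones by limma, 755 at an unadjusted p under 0.05 and a smallest adjusted p of 0.054. The called clones' differences were smaller with their errors unchanged, and fewer clones over the whole array had a small p (1398 before), which raises every adjusted p. The 3 arrays that stand apart were LL week 3 replicate 1, FL week 1 replicate 4 and FL week 7 replicate 3, so only 1 of them is of that age. Without these 3 arrays, the clones kept a median of 97.7%, and all 19 were among 128 called. This argues against FL week 1 replicate 4 alone as the cause. The log ratios of FL week 1 replicates 1, 2 and 3 correlated with the other arrays at a mean r of 0.18, 0.25 and 0.28. Those of LL at week 1 did so at 0.34 to 0.39. A fault shared by the FL arrays of week 1 was not tested by leaving out 1 of them. A difference between the lines may remain as an explanation, and a partial effect of array signal stays open.

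Between weeks 1 and 7, the called clones kept a median of 99.9% of their log2 difference with the array signal as a covariate. All 202 were among 304 called. Mean signal over background was 3.96 in FL and 6.05 in LL at week 1, and 4.98 and 4.97 at week 7. Averaged over the lines it differed little between these ages, so the covariate could remove little and the test does not decide. For HBBA, a smaller share of blood in the tissue at week 7 could lower the transcript, and would lower the alpha globin HBA1 by as much. HBA1 differed by -0.31 ± 0.11 against -1.35 ± 0.15 for HBBA (SE). The other 4 erythrocyte genes tested did not fall as HBBA did: SLC4A1 gave -0.08 ± 0.15, CA2 -0.01 ± 0.08, H1F0 -0.17 ± 0.25 and EPB41 0.09 ± 0.11. These values have limits. An equal change would have needed a mean signal of 83663 per pixel at week 1 for HBA1 and 98109 for CA2. The brightest spots of those arrays had 55641, so a fall of full size could not have shown. The mean signal of HBA1 was 34388 at week 1 and 32868 at week 7. It lay below the brightest spots, so this limit alone does not account for its smaller fall. SLC4A1, H1F0 and EPB41 lay near background, above it on 5, 6 and 5 of 8 week 1 arrays. At week 7 they were above it on 2, 3 and 3 of 8, where a fall shows little. HBBA itself was above background on 7 of 8 week 1 arrays and 5 of 8 week 7 arrays. An equal change would have needed 13854 per pixel at week 1 for EPB41, close to the 13027 for HBBA. Dimness alone therefore does not account for the value of EPB41. HBA1 thus argues against a smaller share of blood as the whole of the fall of HBBA, though it is 1 gene. A part played by blood and a change in globin expression cannot be told apart. Age itself stays open as an untested explanation for the other genes.

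The unnamed clone with the largest fitted fall shares its place in its block with NFASC, TOP2A and STK10 in the next blocks, and TOP2A and STK10 fell with age as well, so the arrays were compared within groups. The deviations from the group means correlated with those of the unnamed clone at r = 0.401 for NFASC (permutation p = 0.15, adjusted 0.225, rho = 0.332, p = 0.109, adjusted 0.164, n = 32), 0.0837 for TOP2A (p = 0.629, adjusted 0.629, rho = 0.151, p = 0.427, adjusted 0.427, n = 32) and 0.533 for STK10 (p = 0.00936, adjusted 0.0281, rho = 0.632, p = 0.00071, adjusted 0.00213, n = 31), over 3 relations with 100000 resamples within groups. Without the 2 arrays farthest from the median, r was 0.412, 0.0623 and 0.505. Clones at one place in blocks of the same grid row correlated in general, with a mean r of 0.16 and a 95th percentile of 0.668 (6338 pairs), against 0.0672 for blocks at least 5 apart and -0.00345 for random pairs. The value for STK10 lies above 86.6% of those same-place pairs, so material carried over between neighbouring wells or pins could contribute, but it cannot be told apart from a position effect over the whole array for any of these genes.

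Other groupings of the same arrays were counted for each result. No other grouping gave as many clones for the line effect across the ages (4 clones, highest other 1, as large in 1 of 100 groupings), for week 1 (19, highest other 2, 1 of 35), for age over all weeks (73, highest other 13, 1 of 100), for weeks 1 to 7 (202, highest other 52, 1 of 100) and within LL (6, highest other 1, 1 of 35). This makes chance less likely but does not exclude it. With 35 groupings, 1 of 35 is the smallest share possible, and no correction was made over the results compared. For weeks 1 to 3 (11 clones), the count was as large in 4 of 100 groupings, and another grouping gave 39, so chance is not excluded there either. Nor is chance excluded within FL (86 clones, as large in 4 of 35), where a grouping of FL week 1 replicates 2, 3 and 4 with FL week 7 replicate 3 gave 715. The groupings that gave 227, 313 and 715 each placed FL week 7 replicate 3 with most of the FL week 1 arrays, and the cause was not tested. Chance cannot be excluded for the gene lists, where the real value was 1 between the lines (as large in 33 of 100, highest other 4) and 1 with age (36 of 100, highest other 4). Results of 0 clones were as large in all groupings, namely 35 of 35 at weeks 3, 5 and 7 (highest other 1 each) and 100 of 100 for the interaction (highest other 1), weeks 3 to 5 (highest other 1) and weeks 5 to 7 (highest other 3).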

How the results depend on the processing

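Chosen after the results were seen were the kept X, Y and A quality letters, the authors' log2 ratios, the fit without the 3 arrays that stand apart, the signal covariate and the lists without TOP2A. Counts are of clones past the threshold, in the order of the report, and the cause of a change was not tested unless stated. The counts in the report were 4 across the ages, 19 at week 1, 0 at weeks 3, 5 and 7 and for the interaction, 73 over all ages, 202 for weeks 1 to 7, 11 for weeks 1 to 3, 0 for the later steps, 6 within LL and 86 within FL, and 1 list each for line and age.

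Without background subtraction, the counts were 46 at week 1, 124 over all ages, 489 for weeks 1 to 7 (199 of the 202 among them), 24 for weeks 1 to 3, 13 within LL and 186 within FL. Print-tip loess gave 26 for weeks 1 to 3, 3 lists for line and 0 for age. Median centring gave 30 at week 1, 42 over all ages and 74 for weeks 1 to 7, and scaling between arrays 3, 46 and 130, with 2 for weeks 3 to 5 and 47 within FL. With no filter on dim clones there were 2 across the ages, 1 at week 7, 17 for weeks 1 to 3 and 0 lists for age. The stricter filter, which tests fewer clones and none of the 4 called across the ages, gave 0 across the ages (203 at an unadjusted p under 0.05, limma), 3 at week 1, 21 over all ages, 2 for weeks 1 to 3, 9 within FL and 0 lists for age. Keeping the X, Y and A letters gave 1 at week 5 and 0 lists for age. The authors' log2 ratios gave 0 across the ages (421 at an unadjusted p under 0.05, limma), 1 at week 1, 310 for weeks 1 to 7 and 13 within LL. The 4 clones called across the ages were not tested with these ratios, so that 0 is not a failed retest.

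Array weights gave 31 at week 1, 3 at week 5, 4 at week 7, 5 for the interaction, 411 over all ages, 1011 for weeks 1 to 7, 186 for weeks 1 to 3, 112 within LL, 476 within FL and 0 lists for age. The signal covariate gave 0 at week 1 (755 at an unadjusted p under 0.05, limma), 304 for weeks 1 to 7, 24 for weeks 1 to 3, 1 for weeks 3 to 5 and 2 lists for line. Without the 3 arrays that stand apart there were 128 at week 1, 5 for the interaction, 142 over all ages, 507 for weeks 1 to 7, 61 for weeks 1 to 3, 329 within FL and 0 lists for age. At a threshold of 0.10 there were 108, 7, 127, 440, 37 and 173 for these, with 1 for weeks 3 to 5 and 12 within LL. Only the groups compared, which leaves fewer arrays, gave 9 at week 1, 25 for weeks 1 to 7, 2 for weeks 1 to 3, 2 within LL and 1 within FL. An estimated correlation gave 0 lists for line and 0 for age, and leaving TOP2A out of the lists 0 for age. An offset of 10 and spots with only B or C letters moved none of these counts by over 1.5 times.

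The replicate block gave 2 across the ages, 37 at week 1, 2 for the interaction, 306 for weeks 1 to 7 and 22 for weeks 1 to 3, and moved no other count by over 1.5 times. The replicate numbers were not taken to pair the arrays, since only 52 of 112 same-numbered pairs of arrays had deviations from the group means that correlated over 0.1. Same-numbered arrays still resembled each other more (mean r = 0.09) than arrays of different numbers (85 of 336 pairs over 0.1, mean r = -0.03), and 17 of 32 arrays matched their own number best among 4 numbers, so part of the spread between arrays goes with the number.

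Leaving out 1 array gave 2 to 5 clones across the ages, 2 to 176 at week 1, 0 to 1 at week 3, 0 to 0 at weeks 5 and 7, 0 to 30 for the interaction, 27 to 208 over all ages, 65 to 535 for weeks 1 to 7, 5 to 76 for weeks 1 to 3, 0 to 2 for weeks 3 to 5, 0 to 0 for weeks 5 to 7, 3 to 9 within LL and 20 to 414 within FL, and 1 to 3 lists for line and 0 to 1 for age. The report names the arrays that moved each count. The mean correlation of line effects between weeks was 0.00, lay between -0.03 and 0.08 over the alternatives and between -0.04 and 0.12 with 1 array left out.

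The share of higher calls moved with the scaling. For weeks 1 to 7 it was 123 higher and 79 lower, against 57 and 17 with median centring and 247 and 242 without background subtraction. Within FL it was 56 and 30, against 42 and 52 with median centring and 101 and 85 without background subtraction. At week 1 it was 1 and 18, against 5 and 25 with median centring, for weeks 1 to 3 it was 6 and 5, against 4 and 5 with scaling and 18 and 8 with print-tip loess, and within LL it was 2 and 4, against 8 and 5 without background subtraction and 4 and 4 with print-tip loess.

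Among the named genes, those past the threshold kept their direction under all settings. Signs turned for genes fixed by name that did not pass. GFAP across the ages gave 0.057 with median centring, 0.031 with the authors' log2 ratios, 0.094 with array weights, 0.023 with the signal covariate and 0.065 without the 3 arrays that stand apart. POMC across the ages gave -0.0067 with scaling, -0.021 with array weights and -0.0017 without those 3 arrays. With age, INSR gave 0.031 with scaling, MBP 0.0027 with the authors' log2 ratios, 0.060 with array weights and 2.8e-05 without those 3 arrays, and TTR -0.011 with print-tip loess, -0.024 with median centring and -0.14 with scaling. With 1 array left out, GFAP lay between -0.12 and 0.057, POMC between -0.012 and 0.048, INSR between -0.11 and 0.048, MBP between -0.090 and 0.026, and TTR between -0.087 and 0.21. The cause was not tested. Of the calls that could be tested again, 37 of 48 were lost with only the groups compared, 11 of 28 with the authors' log2 ratios, 19 of 52 with the signal covariate, 18 of 52 with scaling, 17 of 52 with median centring and 14 of 52 with no filter on dim clones, among others, and 323 of 1664 with 1 array left out. In the authors' deposited table, 3 of 4 named genes across the ages and 29 of 30 with age had the same direction, the exceptions being GFAP and MBP. The 4 across the ages were genes fixed by name that did not pass. A further 5 clones had no values there in each comparison, among them all 4 that passed across the ages. Low signal over background limits dim clones, whose log2 values are of uncertain size where no array of a group was above background.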

Other observations

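The values for list members at week 1 and within FL were read after the counts were seen.

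At week 1, genes of several further lists differed between the lines when adjusted over the list alone, and 0 of them passed over all genes. Genes of synaptic vesicles and exocytosis were lower in FL in 4 cases, among them NSF, the ATPase that takes apart used fusion complexes (log2 -1.06), the vesicle protein VAMP2 (-0.61), the active zone protein PCLO (-0.40) and AP2B1 of the endocytic adaptor (-0.39). The chaperones HSP90B1 (-0.85), CANX (-0.81) and AHSA1 (-0.66) of the heat shock list were lower too. So were the thyroid hormone receptor THRA (-1.33), the cannabinoid receptor CNR1 (-0.32), the secretory granule chaperone SCG5 (-0.67), FDFT1 of cholesterol synthesis (-0.60) and the clock output factor HLF (-0.47). CGA, the common subunit of pituitary glycoprotein hormones, was higher in FL (0.93), as was the laminin LAMB1 (0.50). The median Cy3 signal over background was 3.96 ± 0.718 in these FL arrays and 6.05 ± 1.76 in the LL arrays (SD, n = 4 each).

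Within FL, 2 further genes of the fixed lists passed over all genes between weeks 1 and 7 by limma with the clone that stood for the gene. Clones of the list members DPYSL2, CRMP1, NAPB and CLU that did not stand for their genes passed there as well. NSF rose (log2 1.05 ± 0.24, 4 of 4 arrays, adjusted p = 0.0289), against 0.16 ± 0.24 in LL, and the interaction had an adjusted p of 0.446. NKX6-2, a transcription factor of the oligodendrocyte lineage, fell (-0.71 ± 0.17, 4 of 4 arrays, adjusted p = 0.0348), against -0.06 in LL, and the interaction had an adjusted p of 0.74. A difference between the lines in these changes is therefore not shown. Chance cannot be excluded for the count within FL that these calls belong to (86 clones, as large in 4 of 35 groupings of the arrays, highest other 715), and 1 clone passed with only the groups compared in the fit. With the lines averaged, the thyroid hormone-binding protein CRYM rose (0.53) and the glutamate receptor subunit GRIA2 fell (-0.54) adjusted over their lists alone, and neither passed over all genes (adjusted p = 0.0509 and 0.117).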
